A study of Caenorhabditis elegans with 2 samples.

How the data were processed

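Chromatin immunoprecipitation followed by sequencing (ChIP-seq) measured where UNC-62, a homeodomain protein of the MEIS and Homothorax type, was bound in the genome of second-stage (L2) larvae of the nematode Caenorhabditis elegans. The worms were of strain OP600, which carries an integrated transgene with unc-62 joined to TY1, EGFP and FLAG tags, together with unc-119 sequence. Whole animals of both sexes were used. The labels describe the experiment as directed at the EGFP fusion and list unc-62 under antibody, and the antibody itself is not given in the sources used here. The series holds 1 group of 2 biological replicates from separate biosamples, with a library size range of 150 to 350 bp per the labels. There was no second condition, so the comparisons made were between the replicates and between the reproducible peaks and lower-ranked candidate peaks of the same libraries.

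The deposited files are peak lists in narrowPeak form for 2 genome builds, ce11 and ce10. For each build the authors deposited a candidate list per replicate, a candidate list from both alignments pooled, and a list of reproducible peaks, the optimal set of an irreproducible discovery rate (IDR) procedure, per the labels and accompanying notes. The candidate lists also hold background peaks that serve as input for that procedure. Each peak has a signal value deposited by the authors, made against a control file, and its scale differs between lists, so it was used here only to describe and rank peaks within a list. Each peak also has a deposited −log10 q value, which was tied at its highest value of 2.40 in all 414 reproducible peaks and so gave no order. The aligner, the peak caller, the IDR threshold and the read depth are not given in the sources used here. The control library was not analysed here. With peak lists in place of reads, the depth behind each peak is unknown, and no value here carries an error from read counts.

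Build ce11 was used throughout, with the WBcel235 genome sequence and Ensembl gene annotation, which is the same assembly. All ce11 peaks lay within the lengths of its chromosomes. The ce10 lists were used only where no annotation was needed, and no coordinates were converted. Coordinates are printed counting from 1.

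Peaks were ranked by signal value. For the replicate comparison each replicate list was limited to its 414 highest peaks, as many as there were reproducible peaks, and a peak was shared when it overlapped by at least 1 bp. The expected overlap came from 100 random placements of the replicate 2 peaks along their own chromosomes. Reproducible peaks were compared with the 27554 pooled candidates that overlapped none of them, called lower-ranked candidates below. Summits were assigned to coding exons, UTRs, introns or intergenic sequence of protein-coding gene models, in that order of priority. A promoter summit lay from 1000 bp upstream to 200 bp downstream of the 5' end of a protein-coding transcript. Motifs were searched on both strands within 100 bp of the summit. A gene was called bound when its 5' end was the nearest among protein-coding and microRNA genes, within 5000 bp of a reproducible summit; the background was every gene so placed for at least 1 pooled candidate. Nearness does not establish that a gene is a target. Small RNA genes were counted within 500 bp, and candidates around unc-62 and unc-119 within 20000 bp.

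Shares have exact (Clopper-Pearson) 95% binomial intervals. Comparisons of shares used two-sided Fisher's exact tests on peaks or genes, with Benjamini-Hochberg adjustment within each family. Odds ratios have Woolf intervals, or exact conditional intervals where a cell of the table was under 5. Peaks and genes are not biological replicates, so these p-values describe the peak lists of this experiment. The 28 gene lists (12 by name, 16 by name pattern), the motifs, the windows and the first set of alternative settings were fixed before the data were examined. So was the rule for named genes, which takes the nearest protein-coding gene of the 25 reproducible peaks with the highest signal, up to 4 members by signal of each list of fewer than 40 genes, up to 4 members of each larger list that passed its test, and the transgene loci. Genes named outside that rule are said to be so.

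A comparator matched on GC content and promoter location was added after the data were seen: 5 lower-ranked candidates per reproducible peak, of the same promoter status and the closest GC content within 100 bp of the summit. Many candidates share a GC value. In a first version, ties went to the candidates with the higher signal, which gave a matched set with a median rank of 1763. Ties were then broken at random, which gave a median rank of 12245, and this version is used; the first is kept as a named alternative. The random draw was repeated to give 20 matched sets.

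The overlap, nearest-gene, promoter and gene list steps were tested on simulated data. All 104 planted overlaps among 414 simulated peaks were recovered, and 300 of 300 nearest distances matched a direct search. For promoter share, sets drawn from the 28005 pooled candidates with a planted odds ratio of 3 gave a median estimate of 3.07, and with a planted odds ratio of 1, 4 of 100 draws passed 0.05. With 1 list, the ribosomal protein genes (48 members), planted at 8 times the odds among 12713 genes, that list was called in 93 of 100 draws. Other lists were called 5 times in all. Recovery of smaller lists was not simulated. All genes outside the planted list had equal odds in these draws, so unequal numbers of candidates per gene were not simulated. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used.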

Results

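The reproducible set held 414 peaks on build ce11, with signal values from 28.2 to 174 and a median of 37.5. The pooled candidate list held 28005 peaks with a median signal of 9.02, and each replicate's candidate list held 30000. All 414 reproducible peaks had the same coordinates and signal in the pooled list, where they occupied ranks 1 to 414. The reproducible set therefore equals the 414 pooled peaks with the highest signal. Of the 414 peaks, 408 were 336 bp wide and 6 were narrower, and together they covered 138 kb.

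Of the 25 strongest peaks, 13 lay at promoters, 3 of them of ribosomal protein genes, 6 in other intergenic sequence, 4 in introns and 2 in UTRs. The highest, at chromosome III 12612587 to 12612737, lay in an intron of Y111B2A.12 with a signal of 174. The next lay in intergenic sequence 160 bp upstream of Y17G9B.5 (chromosome IV 4750010 to 4750158, signal 150). A peak with a signal of 149 lay 259 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit (chromosome III 3867508 to 3867649). These peaks held ranks 1 to 3 in each replicate as well. Peaks upstream of rpl-15 (signal 107) and rpl-35 (signal 91.5), which encode proteins of the same subunit, ranked 6 and 16 in the pooled list. An intronic peak in zfp-1, a gene for a zinc finger chromatin protein, ranked 8 with a signal of 107, and a peak in an annotated 5' UTR of unc-62 itself ranked 9 with a signal of 103.

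Among the 25 strongest peaks, others lay upstream of nspc-17 on the X chromosome, the AAA ATPase gene cdc-48.1, tasp-1, egg-5, the translocon subunit gene sec-61.G, the Pumilio family gene puf-9, tag-340, the cytochrome c oxidase subunit gene cox-5A and the autophagy gene lgg-2, all within 1000 bp of the 5' end. The egg-5 peak was also within 500 bp of the spliced leader RNA gene sls-2.4. Intergenic peaks farther from a protein-coding 5' end were nearest to W02H3.3 (3994 bp), ZK899.6 (2505 bp), K02D3.1 (6059 bp), M106.2 (1331 bp), the zinc finger gene sma-9 (3017 bp) and xol-1, the switch gene of sex determination (4916 bp). The xol-1 peak ranked 4 in replicate 1 and 125 in replicate 2. The remaining peaks of this group lay in a 3' UTR of T23G4.127, an intron of pqn-41, and an intron of mom-1 with cest-16 as the nearest 5' end.

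The replicates shared 48.3% of their 414 strongest peaks (200 of 414, exact 95% interval 43.4 to 53.2). Random placement gave a mean of 1.21 shared peaks, and at most 4 in 100 placements. Agreement was higher among the strongest peaks: 62 of the top 100 of replicate 1 overlapped the top 100 of replicate 2, against 575 of the top 2000 (28.7%). Of the reproducible peaks, 334 were among the top 414 of replicate 1 and 249 among the top 414 of replicate 2, while 31 were in neither. All 414 overlapped a candidate of replicate 1 and 407 a candidate of replicate 2. A peak called reproducible therefore need not rank high in both replicates. Across those 407 peaks the Spearman correlation of the replicates' signal values was 0.35, a description across peaks, which are not independent replicates and were selected on pooled signal. It was 0.24 across 8642 pooled candidates with a counterpart in both replicates.

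**Figure D1:**
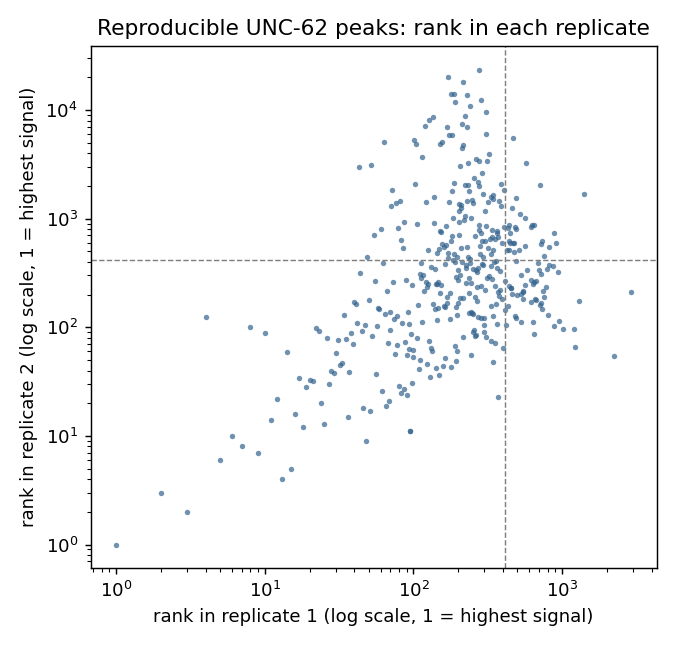
Rank of each reproducible peak among the candidates of replicate 1 (horizontal, log scale) and replicate 2 (vertical, log scale), 1 point per peak with a candidate in both (407 peaks). Dashed lines mark rank 414, and 200 peaks lie within both lines.

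Reproducible peaks lay at promoters more often than lower-ranked candidates did. Promoter summits made up 51.9% of reproducible peaks (215 of 414, 95% interval 47 to 56.8) and 28.6% of lower-ranked candidates (7869 of 27554), an odds ratio of 2.70 (95% interval 2.22 to 3.28, Fisher's exact test, p = 4.7e-23). Intergenic summits made up 71.7% of reproducible peaks against 38.7% of candidates. Coding exons held 1.45% (6 peaks) against 23.4%, introns 21.7% against 32.2%, 5' UTRs 3.86% against 1.77% and 3' UTRs 0.966% against 3.73%. The median distance from the summit to the nearest protein-coding 5' end was 785 bp for reproducible peaks and 1238 bp for candidates.

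**Figure D2:**
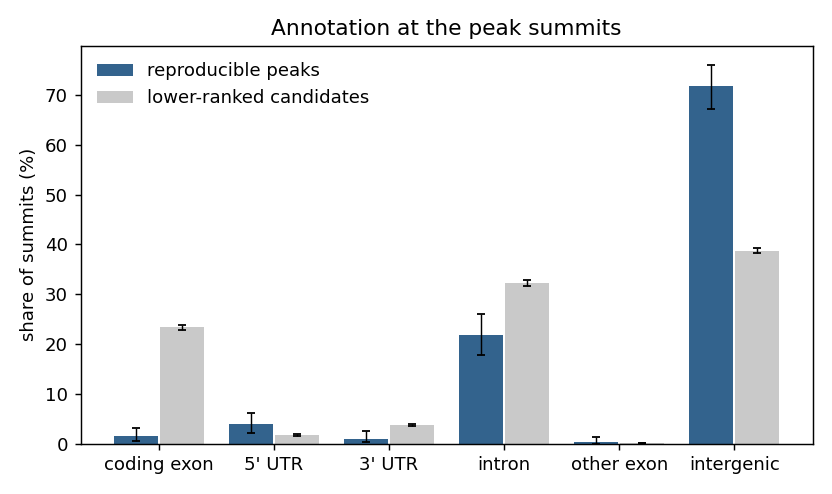
Share of summits (%) in each class of protein-coding gene annotation for 414 reproducible peaks (blue) and 27554 lower-ranked candidates (grey), with exact 95% binomial intervals as error bars. Intergenic sequence held 71.7% of the reproducible and 38.7% of the lower-ranked summits.

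No chromosome had a share of reproducible peaks that passed the test. The X chromosome held 81 reproducible peaks (19.6%, 95% interval 15.9 to 23.7), against 21.05% of lower-ranked candidates (odds ratio 0.91, 95% interval 0.71 to 1.17, Fisher's exact test, adjusted p = 0.76). Chromosome III held 16.9% against 13.8% and chromosome IV 12.8% against 16.1%, both with an adjusted p of 0.22 by Fisher's exact test. Chromosome I held 16.2% against 14.3%, chromosome II 15.7% against 15.3% and chromosome V 18.8% against 19.4%, with adjusted p-values of 0.58, 0.85 and 0.85 by Fisher's exact test.

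The MEIS core motif TGACAG lay within 100 bp of the summit in 11.6% of reproducible peaks (48 of 414, 95% interval 8.67 to 15.1) and 7.92% of lower-ranked candidates. The odds ratio was 1.52 (95% interval 1.13 to 2.07, Fisher's exact test, adjusted p = 0.025). Among 179 control 6-mers with the same letters, 27 had a higher odds ratio, and the control median was 1.08. Among the 207 strongest reproducible peaks the odds ratio was 2.37 (adjusted p = 6.1e-05 by Fisher's exact test). The call was lost against candidates matched on GC content and promoter location (odds ratio 1.31, adjusted p = 0.17 by Fisher's exact test) and in the top 414 peaks of replicate 2 alone (1.28, adjusted p = 0.29 by Fisher's exact test). It was also lost within 200 bp of the summit (1.19), against the 13777 lower-ranked candidates with the higher signal (1.45) and against matched candidates with GC ties going to the higher signal (1.09), with adjusted p-values of 0.45, 0.060 and 0.76 by Fisher's exact test. The longer site TGATTGACAG occurred in 1 reproducible peak and 12 candidates, TGATNNAT in 18.6% against 16.9% and the GATA motif WGATAR in 34.1% against 37.5%, with adjusted p-values of 0.22, 0.36 and 0.22 by Fisher's exact test.

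GAGAGA was the motif with the largest difference of the 5 tested, in 50.7% of reproducible peaks (210 of 414, 95% interval 45.8 to 55.6) and 14.05% of lower-ranked candidates (odds ratio 6.30, 95% interval 5.18 to 7.66, Fisher's exact test, adjusted p = 1.1e-67). The GC content within 100 bp of the summit was 44.9% ± 6.7 (SD, 414 peaks) and 36.3% ± 7.1 (SD, 27554 candidates). Against the matched candidates the odds ratio for GAGAGA was 3.07 (95% interval 2.47 to 3.81), and 1.88 (95% interval 1.52 to 2.33) where ties in GC content went to candidates of higher signal.

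**Figure D3:**
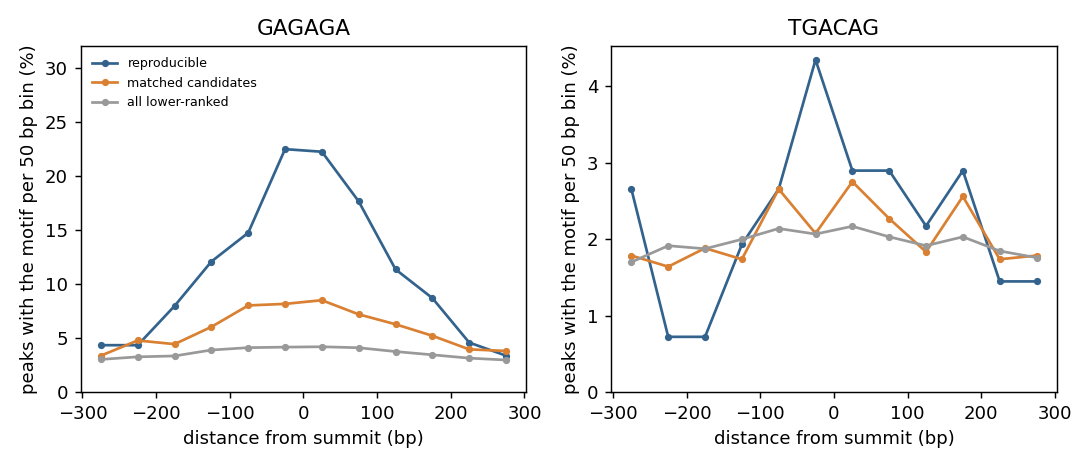
Share of peaks (%) with GAGAGA (left) or TGACAG (right) in each 50 bp bin by distance from the summit (bp), for reproducible peaks (blue), 2070 candidates matched on GC content and promoter location (orange) and all lower-ranked candidates (grey). Within 50 bp of the summit GAGAGA occurred in 36.7% of reproducible peaks and TGACAG in 6.76%.

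Reproducible peaks lay near 359 of the 12713 background genes (2.82%), and 4 of 28 gene lists passed the test. A gene near more candidates had more chances to be called bound, and the test did not adjust for that. The MEIS, PBC and Hox list, which holds unc-62 and genes for its homeodomain partners, had 4 of 10 background members bound (odds ratio 23.2, 95% interval 4.79 to 98.2, Fisher's exact test, adjusted p = 0.0011). They were unc-62, the PBC gene ceh-20 (729 bp upstream, chromosome III 6978987 to 6979322, signal 73.0), and the Hox genes ceh-13 (744 bp upstream, chromosome III 7554748 to 7555083, signal 52.1) and lin-39 (5' UTR, chromosome III 7534632 to 7534967, signal 42.96). The unc-62 member lies at a locus that the transgene also carries. Without the peaks around unc-62 the count was 3 of 10 (odds ratio 14.9, Fisher's exact test, adjusted p = 0.016).

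Heterochronic genes, which time larval development, had 5 of 13 members bound (odds ratio 21.8, Fisher's exact test, adjusted p = 0.00052). The microRNA gene mir-241 had a peak 432 bp upstream (chromosome V 14366547 to 14366882, signal 48.1). Peaks lay in an intron of lin-42 (chromosome II 1246887 to 1247222, signal 43.5), in an intron of lin-28 28 bp upstream of a transcript's 5' end (chromosome I 8409780 to 8410115, signal 43.1) and 1414 bp upstream of lin-41 (chromosome I 9343742 to 9344077, signal 35.4). The fifth member was lin-14, named here after its values were seen.

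Ribosomal protein genes had 8 of 48 members bound (odds ratio 7.02, 95% interval 3.26 to 15.1, Fisher's exact test, adjusted p = 0.00074). The strongest after rpl-3, rpl-15 and rpl-35 was rps-1, with an intergenic peak 247 bp upstream (chromosome III 4475503 to 4475838, signal 56.2). Serpentine receptor genes, a large family of chemoreceptor-type genes, were bound less often than the background, at 6 of 628 (odds ratio 0.32, 95% interval 0.14 to 0.72, Fisher's exact test, adjusted p = 0.013). The members with the highest signal were srlf-26 (63.1), srh-16 (35.2), srsx-22 (33.1) and srh-2 (29.6). No gene list or small RNA class was tested against the candidates matched on GC content and promoter location. Accessible chromatin and signal shared with the control library or with other factors were not tested for any list or class.

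The other lists did not pass in the main comparison. The dauer and insulin list had 3 of 20 members bound (daf-14, daf-5 and daf-16, all with intronic summits) and the homeobox list 6 of 73, each with an adjusted p of 0.083 by Fisher's exact test. The daf-14, daf-5 and daf-16 peaks ranked 122, 63 and 294 in replicate 1 and 262, 5064 and 1678 in replicate 2. Bound members of the homeobox list include unc-62, ceh-20, ceh-13 and lin-39, the 4 bound members of the MEIS, PBC and Hox list, so the 2 lists are not separate results. The homeobox list passed in 5 of 7 alternative settings, and the Wnt and neuron lists in the top 414 peaks of replicate 2 alone. The dauer and insulin list passed with all genes as background, and the histone and heat shock lists when every gene with a summit from 2000 bp upstream to 500 bp downstream counted as bound. The Wnt list had 2 of 21 (mig-5 and cam-1), neuron markers 2 of 30 (rgef-1 and unc-104), body wall muscle 1 of 20 (egl-15), somatic gonad and vulva 1 of 18 (fos-1), heat shock genes 2 of 15 (hsp-3 and hsp-1) and proteasome subunits 1 of 16 (rpn-3). In replicate 2 the rgef-1 and unc-104 peaks ranked 173 and 2034. The hsp-3 peak and the strongest hsp-1 peak ranked 396 and 14184 there. Nuclear hormone receptor genes had 9 of 186. Of genes named after their values were seen, the histone list had his-37 and his-68 bound of 19, collagens col-17 and col-185 (1.92% of members), neuropeptides ins-13, ins-39 and nlp-40 (2.68%), and F-box genes fbxa-141, fbxb-58 and fbxb-85 of 141. None was bound among the background members of the vitellogenin (3), epidermis (22), intestine (17), pharynx (13), germ line (12), C-type lectin (121), cytochrome P450 (36), major sperm protein (13), vacuolar ATPase (17), hedgehog-related (36) and aminoacyl-tRNA synthetase (20) lists.

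Small RNA genes lay within 500 bp of some reproducible summits. snoRNA genes were near 12 (2.90%, against 0.711% of lower-ranked candidates, odds ratio 4.17, Fisher's exact test, adjusted p = 0.00035). snRNA genes were near 4 (0.966% against 0.192%, odds ratio 5.06, Fisher's exact test, adjusted p = 0.025), which by annotation were 3 peaks at SL2 spliced leader genes of the sls-2 family and 1 at F54D8.7. The snoRNA call was lost in the top 414 peaks of replicate 2 alone (odds ratio 1.99) and among the 207 strongest reproducible peaks (2.05), and the snRNA call in the top 414 of replicate 1 alone (3.72) and within 1000 bp (3.48). MicroRNA genes were near 4 peaks (mir-241, mir-52, mir-53, and mir-54 with mir-55) and tRNA genes near 8, with adjusted p-values of 0.075 and 0.086 by Fisher's exact test. In the top 414 peaks of replicate 2 alone the microRNA odds ratio rose from 3.12 to 5.69 and passed (adjusted p = 0.0019 by Fisher's exact test). The small RNA genes and the host gene mom-1, apart from mir-241, fall outside the rule for named genes and were named after their values were seen. No rRNA gene was near a reproducible peak, which allows a share of up to 0.887% (exact 95% interval).

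Candidate peaks were dense around unc-62 (chromosome V 4497461 to 4511449, plus strand). The gene with 20000 bp on each side held 46 pooled candidates, or 0.85 per kb, above 99.99% of equally drawn windows around protein-coding genes, whose median was 0.27 per kb. Of these, 6 were reproducible, including adjacent narrow peaks at 4507919 to 4508052 and 4508193 to 4508367. In replicate 2 these narrow peaks ranked 30 and 4, while the reproducible peak at 4507198 to 4507533 ranked 20358. The window around unc-119 (chromosome III 10902641 to 10908935) held 15 candidates and no reproducible peak, or 0.32 per kb. In the candidate list of replicate 2 alone it held 9, or 0.19 per kb, below the median of 0.29 per kb in that list.

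**Figure D4:**
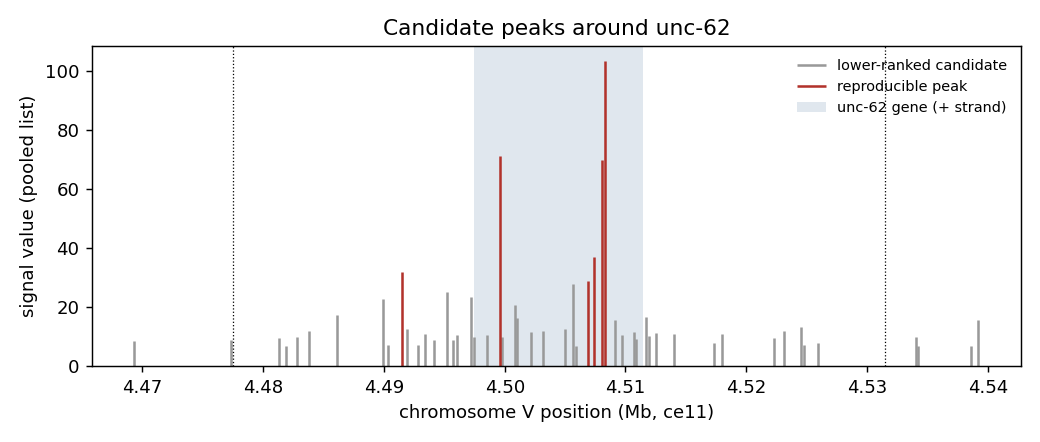
Signal value in the pooled list (vertical) of candidate peaks by position on chromosome V (Mb, ce11), with reproducible peaks in red, lower-ranked candidates in grey, the unc-62 gene shaded and dotted lines 20000 bp beyond its ends. The window between the dotted lines holds 46 candidates, 6 of them reproducible.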

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

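The comparators matched on GC content, the tests without the peaks around unc-62 and all GAGAGA alternatives were chosen after the data were seen. Of 107 alternative values over 18 results, 86 changed little. A tested value then kept its direction and its side of the threshold, a value without a test stayed within the 95% interval of the report's value, and a count stayed within 1.5 times the report's count. A count that changed little does not mean that the same lists or peaks were counted. The promoter odds ratio stayed above 1 and past the threshold in every alternative run, from 2.13 (promoters of 2000 bp upstream to 500 bp downstream) to 3.38, as did GAGAGA, from 1.88 to 7.09. The lower end for GAGAGA came from the matched set whose GC ties went to the higher signal; random ties gave 3.07. The cause was not tested for the changes that follow. The TGACAG odds ratio rose to 2.37 in the 207 strongest reproducible peaks and still passed within 50 bp of the summit (1.71). It no longer passed within 200 bp of the summit (1.19), against the 13777 lower-ranked candidates with the higher signal (1.45) or against matched candidates (1.31 with random ties, 1.09 with ties to the higher signal), and it ranged from 1.28 to 1.83 when either replicate was left out, failing without replicate 1. The X chromosome odds ratio changed direction without either replicate, from 0.91 to 1.03 and 1.05, and passed in no alternative run. The tRNA odds ratio changed direction from 2.02 to 0.50 in the 207 strongest reproducible peaks. Summits within 100 bp lowered the replicate overlap to 41.5%, and a top 207 in place of 414 raised it to 53.6%. By construction the strongest reproducible peaks number 207. Small RNA classes past the threshold numbered 2 in the report, 1 in the 207 strongest peaks, 1 within 1000 bp, and 1 to 2 when either replicate was left out. Within 1000 bp the class lost was snRNA (odds ratio 3.48, adjusted p = 0.054 by Fisher's exact test), and the 2 classes without replicate 1 were snRNA and microRNA, not snoRNA. Gene lists past the threshold rose from 4 to 7 when every gene with a summit from 2000 bp upstream to 500 bp downstream counted as bound, and ranged from 4 to 7 when either replicate was left out, with 7 without replicate 1. The 4 lists of the report passed in all 7 alternatives run, with odds ratios from 14.9 to 46.1 for MEIS, PBC and Hox genes, 12.4 to 35.1 for heterochronic genes, 6.13 to 14.1 for ribosomal protein genes and 0.10 to 0.32 for serpentine receptor genes. The homeobox list was gained in 5 of the 7, the Wnt and neuron lists without replicate 1, the dauer and insulin list with all genes as background, and the histone and heat shock lists in the 2000 bp window. Read depth is unknown, so its effect on the peak lists was not assessed.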

Other observations

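The screen of all 6-mers, the TGATNNAT comparison with matched candidates and the test of reproducible peaks within the unc-62 gene were chosen after the results were seen; the other tests below were written before theirs were seen, but the patterns they address had been seen, and the matched comparator was first run with GC ties going to the higher signal and then corrected to random ties.

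The 6 narrow reproducible peaks ranked 1, 2, 3, 9, 13 and 42 by signal, and every 36-mer within 100 bp of their summits occurred once in the genome. Across all 2080 6-mers, ACGCAG had the lowest p-value against the matched candidates (32.1% of reproducible peaks against 10.1%), followed by AGAGAG (47.1% against 21.1%) and GAGAGA. In the same comparison 137 6-mers were more frequent and 147 less frequent at an adjusted p under 0.05 by Fisher's exact test, and TGACAG ranked 750 by p-value. The PBC and Hox site TGATNNAT, which did not differ from all lower-ranked candidates, was more frequent than in matched candidates (18.6% against 13.2%), with odds ratios from 1.42 to 1.80 over 20 matched sets. For TGATNNAT no values are given with same-letter controls, GC ties going to the higher signal or single replicates. A difference particular to this site is therefore not shown.

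GAGAGA was in 50.7% of reproducible peaks. GC content and promoter location are not the whole source of the difference: against matched candidates the odds ratio fell from 6.30 to 3.07 (95% interval 2.47 to 3.81) and lay between 2.87 and 3.23 over 20 matched sets. With ties in GC content going to candidates of higher signal it was 1.88, in a matched set of median rank 1763 in place of 12245. Every reproducible peak ranks above every lower-ranked candidate in signal, so these comparisons cannot separate GAGAGA from signal. Exact 36-mer repeats of the genome sequence do not account for the GAGAGA difference. Among peaks whose 36-mers were all unique the odds ratio was 6.02 (95% interval 4.76 to 7.61), from 396 reproducible peaks and 1892 candidates of a random sample of 2000. The aligner is not given, and reads placed with mismatches were not tested. Accessible chromatin and signal shared with the control library or with other factors were not tested, and the design names no second group, so no biological explanation was tested.

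TGACAG, the site known for MEIS proteins, may mark direct contact of UNC-62 at some summits, but these lists leave that open. Within reproducible peaks it was 2.15 times as frequent within 50 bp of the summit as around points 250 bp away (95% interval 1.28 to 3.63; 28 peaks). Base composition at the summits was not excluded: 7.82% of the control 6-mers (14 of 179) had a ratio as high. GC content was 47.2% at the summits and 36.2% at the flanking points. The control 6-mers have the letters of TGACAG, and their median ratio was 1.08, so 2.15 was not typical of 6-mers with these letters. Against candidates matched on GC content and promoter location the odds ratio was 1.31 (95% interval 0.94 to 1.84). Over 20 matched sets it lay between 1.19 and 1.46, and 5 sets gave an unadjusted p under 0.05 by Fisher's exact test. The sets share the same reproducible peaks and candidate pool, so they are not independent. The interval includes 1, so GC content and binding cannot be told apart here.

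Part of the density of candidates around unc-62 may come from extra copies of the region in the transgene. The stretches from 5000 to 20000 bp outside the gene held 16 candidates, a density above 97.3% of equally placed stretches around other protein-coding genes. That was 0.53 per kb, against 1.25 within 5000 bp of the gene body. The extent of the inserted unc-62 sequence is not given in the sources used here. The lower density of the flanks therefore does not tell extra copies at the gene from binding there. The window around unc-119, which the labels also place in the transgene, lay above 68.5% of windows in the pooled list, 75.7% in replicate 1 and 14.1% in replicate 2. The species and extent of that unc-119 sequence are not given in the sources used here, so its density says nothing on extra copies of unc-62. Binding within unc-62 itself stays open: 5 of the 6 reproducible peaks of the window lay in the gene body and 1 lay more than 5000 bp from it. The transgene carries the same gene, so peaks from the native and the inserted copies cannot be told apart in these lists.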
